A study of Mus musculus with 7 samples.

How the data were processed

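The samples were 7 libraries of C57BL/6 mouse bone marrow cells, each 1 sorted fraction, prepared with the 10x Chromium Single Cell 3' version 2 kit per the labels. Fractions were total live marrow, Lin-Kit+, Lin-CD45- and 4 Lin-CD45-CD71- preparations (crushed marrow, digested bone chips, flushed undigested and flushed digested marrow). The label of the Lin-CD45- fraction describes sorting CD45-negative cells positive for a DNA dye, which excludes debris. Per the labels, crushed Lin-CD45-CD71- cells were sorted into lysis buffer and the others into saline with 2% serum. The values in the deposited files are counts, unique molecular identifiers (UMIs) per gene and cell, without further normalization. The submitters' processing notes name Cell Ranger 1.2.0 and 2.0.0, R 3.5.0, Seurat 2.3.3 and the mm10 genome, without a role per file. The deposited cells had at least 500 genes each, with at most 4.98% mitochondrial UMIs in the 5 earlier libraries and up to 16.7% in the flushed pair. The 5 earlier files list 16701 genes, each seen in at least 3 cells over those libraries, and the flushed pair 13670, of which 13581 are shared. A deposited joint table of 7497 cells held the same counts as the 5 earlier files. No deposited column was left unmatched.

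Low counts of some abundant genes were absent from 4 libraries. This was checked on genes with at least 100 UMIs in at least 20 cells of a library, with at least 5% of cells at 0, by looking for genes of which no cell held 1 UMI. None was found in Lin-Kit+ marrow (0 of 8786 genes), undigested (0 of 2156) or digested flushed marrow (0 of 5552). Absent genes in a file (Cd4, Cd8a, Ccl21a, Lyve1, Msmp and Mog in the flushed pair) were treated as not listed, not as 0.

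Cells with at least 500 genes and under 10% mitochondrial UMIs were kept, 9899 of 9908, with 4 removed from undigested and 5 from digested flushed marrow. With scanpy 1.11.5 on Python 3.11.15 (anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2), counts were scaled to 10000 per cell and log-transformed. Over 2000 variable genes, leaving out the niche genes, 30 principal components and 15 neighbours were computed, and Leiden clustering was run at resolution 1 with seed 1. Leading genes of a cluster were ranked by the ratio of CPM with 10 added, among genes in at least 25% of its cells. A cluster took the class of the list with the most markers among its 50 leading genes, if these were at least 3, with the lists of T and NK cells, of both erythroid stages and of both fibroblast kinds counted together. It stayed unnamed where another class had more markers among its 10 leading genes, as cluster 27 did with 3 chondrocyte markers. Cluster 23, with 3 markers of the Schwann cell list, was left unnamed by a choice made after seeing its leading genes Mag, Mog and Mobp, which belong to central myelin. No marker list held a niche gene. Shares carry exact Clopper-Pearson 95% intervals, and a share at 0 carries the limit that 3 counts would give. Doublet scores came from Scrublet, and doublets were kept. Its calls were unusable, with 913 of 946 cells called in Lin-CD45- marrow and 31 of 8953 elsewhere.

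Comparisons between libraries used UMIs summed per library, or per library and class, scaled to a total of 1000000 (CPM), and log2 ratios of CPM with 1 added. No test was made between libraries, since each fraction has 1 library. Folds carry exact conditional intervals for a ratio of 2 Poisson counts, CPM carry exact Poisson intervals, and a fold against 0 UMIs is a lower bound against a floor of 3 counts. The comparisons were Lin-Kit+ and Lin-CD45- against total marrow, crushed Lin-CD45-CD71- against Lin-CD45-, bone chips against crushed, digested against undigested flushed, flushed undigested against crushed, and bone chips against flushed digested marrow. Classes were compared where both libraries held at least 50 of its cells. Gene lists fixed before the data were examined were gate genes, immediate early genes, heat shock genes, collagens and matrix, matrix enzymes, niche cytokines, niche growth factors, niche adhesion and Notch ligand genes, haemoglobin genes, cell cycle genes, sources of free RNA and markers of cell classes. Lists of central myelin, peripheral myelin, other neural genes and nuclear transcripts were added after the data were seen. A list's median log2 ratio over members with at least 20 UMIs in 1 library was placed among 10000 random lists of the same size matched on mean expression.

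Named genes followed a rule also fixed before the data were examined. Per comparison these are the 8 highest and 8 lowest log2 ratios among genes with at least 100 UMIs in 1 of the libraries. From each list described, they are also the 2 members with most UMIs and the highest and lowest ratio. Within a class they are the 5 highest and 5 lowest among genes with at least 50 UMIs. In the niche test they are the 8 members with the largest absolute fold change among those past an adjusted p of 0.05 over the list alone, and Cxcl12, Kitl, Il7, Csf1 and Vcam1 in any case. Gate genes are always named. Mitochondrial, ribosomal protein and sex-linked genes were left out of the ranking.

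Niche genes were tested between mesenchymal and endothelial cells with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), on UMIs summed per library and class, with TMM scaling (factors 0.882 to 1.2), filterByExpr and a quasi-likelihood F test, library as a block. It used the 3 libraries with at least 20 cells of both and had 2 residual degrees of freedom. The SE given is the absolute log2 fold change divided by the square root of F. It is approximate, least reliable for genes with 0 or 1 endothelial UMI. Benjamini-Hochberg adjustment was over 10064 genes and over the list alone. The other planned contrasts, LepR-like against fibroblast-like and sinusoidal against arterial, each had 2 of the 3 libraries required, so only ratios are given. Tested on simulated data, the procedure recovered 7% of 100 genes changed 2-fold and 72% of 100 changed 4-fold, with 0 of wrong sign, and also called 10 unchanged genes among the 9664 tested. These simulated calls were adjusted over all 9664 genes, so recovery with adjustment over the list alone is not known. In simulated ratios between libraries, 93.4% to 96.6% of intervals of unchanged genes held 1.

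Alternatives fixed before the data were examined covered the cell filter, the joint table, resolution 0.5 and 2, 1000 variable genes, niche genes used in clustering, each cell assigned alone by marker UMIs, cells weighted equally, totals without globin, mitochondrial and ribosomal protein genes, TMM, 10 CPM added, a minimum of 20 UMIs and thinning to 1000 UMIs per cell. For the niche test they were DESeq2 1.42.0, no filter, no block, at least 50 cells, resolution 2 and each library left out in turn. The setting of at least 50 cells drops crushed marrow, so it is the same fit as leaving that library out, and its values are counted under both names. Others were chosen after seeing the data, namely a limit of 5% mitochondrial UMIs alone, removal of the 5% of cells with the highest Scrublet scores (for the shares and for the niche test), LepR-like cells of cluster 10 only, unnamed clusters left out of the denominator, and genes with absent low counts left out. Figures were drawn with matplotlib 3.10.9.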

Results

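Single-cell transcriptomes were collected from 7 fractions of mouse bone marrow, each sorted by flow cytometry and run as 1 library on the 10x Chromium 3' version 2 chemistry. The animals were C57BL/6, a widely used inbred strain. Total live marrow, Lin-Kit+ progenitors, Lin-CD45- cells and Lin-CD45-CD71- cells came from the liquid that crushed bones release. A further Lin-CD45-CD71- fraction came from the bone fragments left after crushing, digested with collagenase I and dispase. The last pair, also Lin-CD45-CD71-, came from marrow flushed out of the bones, 1 undigested and 1 digested. Lin- cells lacked Ter119, Gr1, B220, CD11b, CD8 and CD4, markers of mature blood cells. Kit is the receptor for stem cell factor, CD45 marks nearly all white blood cells, and CD71, the transferrin receptor, is abundant on erythroid precursors.

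The files held 1161 cells of total marrow, 2599 of Lin-Kit+, 946 of Lin-CD45-, 1057 of crushed Lin-CD45-CD71-, 1734 of bone chips, 613 of undigested flushed and 1798 of digested flushed marrow. In the same order, the summed UMIs (unique molecular identifiers, 1 per captured transcript) were 8665052, 20786829, 23116155, 3957320, 5765620, 1292178 and 3819495. Median UMIs per cell ranged from 24136 in Lin-CD45- through 7124 in Lin-Kit+, 5168 in total, 2953 in crushed and 2787 in chips to 1892 in digested and 1325 in undigested flushed marrow. With 1 library per fraction, no difference between fractions has a replicate check and none was tested. Values in parentheses after a share, a level or a fold are exact 95% intervals (Clopper-Pearson for shares of cells, Poisson for UMIs), which cover counting error only. Levels are UMIs summed over cells and scaled to a total of 1000000 (CPM). Members of a gene list count as higher or lower at a ratio of 2-fold or more, and where a list's median differs with genes at 0 UMIs set to a floor of 3 counts, that floor value follows it. Each median was placed among those of 10000 random lists matched on mean expression, and those printed that reach 1 or -1 lay at percentile 99.8 or above and 0.02 or under. Random lists were drawn gene by gene, while members of a fixed list can rise and fall together between libraries of different cell classes. Extreme percentiles are therefore likely, and they describe these libraries without testing a difference. Cell names carried 4 date-like prefixes. Total and Lin-CD45- marrow shared a prefix, as did crushed marrow and bone chips and the flushed pair, and Lin-Kit+ stood alone.

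In 4 libraries some abundant genes lacked any cell with a low count, a gap whose origin is not given in the sources used here. It covered 43 of 7033 examined genes in total marrow, 67 of 6821 in Lin-CD45-, 23 of 5597 in crushed and 15 of 6297 in chip cells, and these genes held 10.7%, 6.00%, 10.3% and 6.10% of the UMIs. Of the genes named here they included S100a8, S100a9, Camp, Lyz2, Ly6c2, Klf2, Mpo and Elane in total marrow, and Gypa, Hba-a1, Klf1, Rrm2, Birc5, Sparc and Cxcl12 in Lin-CD45-. Crushed marrow lacked low counts of Plp1, Mbp, Aplp1, Vpreb1, Igll1, Cxcl12, Dcn, Col1a1, Bglap and Mmp13, among others, and chips of Plp1, Dcn, Cxcl12, Bglap and Hspa1a, among others. How far their ratios would move with those counts present is unknown.

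Transcripts of the sorted antigens were looked at first. Ptprc, which encodes CD45 and, as an isoform that 3' counts do not separate, B220, stood at 157 (149 to 165) CPM in total marrow and at 0.519 (0.268 to 0.907) in Lin-CD45-, 0.867 (0.282 to 2.02) in bone chips and 3.41 (1.82 to 5.83) in digested flushed marrow. It was higher in crushed Lin-CD45-CD71- marrow, at 18.7 (14.7 to 23.5) CPM, and in undigested flushed marrow, at 83.2 (68.2 to 101) CPM. Tfrc, which encodes CD71, reached 152 (147 to 157) CPM in Lin-CD45- against 11.9 (8.73 to 15.8) in crushed, 4.16 (2.67 to 6.19) in chips, 11.0 (7.94 to 14.9) in digested and 50.5 (39.0 to 64.4) in undigested Lin-CD45-CD71- cells. Kit stood at 43.1 (40.3 to 46.0) CPM in Lin-Kit+ against 10.2 (8.15 to 12.5) in total marrow, and at 49.0 (37.6 to 62.6) in undigested flushed marrow. Ly6c2, a monocyte antigen read by many Gr1 antibodies, was at 965 (912 to 1021) CPM in undigested flushed marrow, 849.9 (831 to 869) in total marrow and 0.525 (0.0635 to 1.89) in digested flushed marrow. Ly6g, the neutrophil antigen, was at 135 (127 to 143) CPM in total and 0.241 (0.0781 to 0.561) in Lin-Kit+ marrow, and Itgam (CD11b) was at 62.1 (57.0 to 67.6) and 5.0 (4.09 to 6.06). Cd4 and Cd8a, at 7.27 (5.59 to 9.30) and 29.3 (25.8 to 33.1) CPM in total marrow, had 0 UMIs in Lin-CD45-, crushed and chip cells and were not listed in the flushed files.

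**Figure D1:**
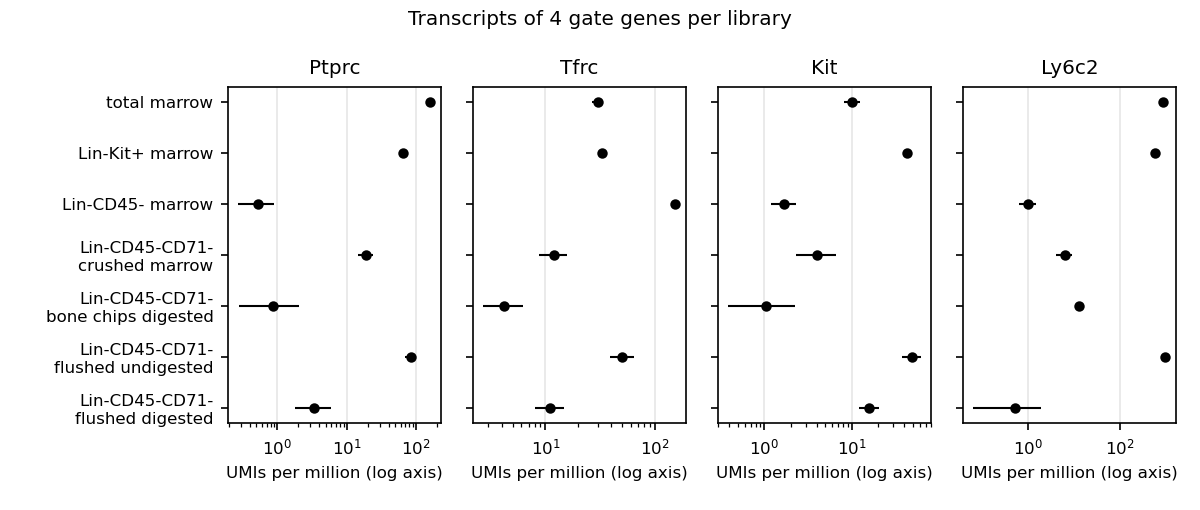
Transcripts of 4 gate genes (Ptprc for CD45, Tfrc for CD71, Kit, and Ly6c2) in the 7 libraries, in CPM on a log axis, with bars for exact Poisson 95% intervals over the summed UMIs of 1 library each. Among the 4 Lin-CD45-CD71- libraries, the undigested flushed one has the highest level of all 4 genes, with Ptprc at 83.2 and Ly6c2 at 965 CPM.

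Clustering of all cells that passed the cell filter gave 31 clusters, of which 26 were assigned to a cell class by fixed markers. Classes are called by their resemblance to known types. A cluster mostly of 1 library may be that library rather than a type, and each sort sets the shares it allows. Total marrow held neutrophil-like cells at 22.1% (19.8 to 24.6), mature B-like at 21.2% (18.9 to 23.7), monocyte-like at 18.8% (16.6 to 21.1) and T or NK-like cells at 18.5% (16.3 to 20.9). Lin-Kit+ marrow held stem or progenitor-like cells at 28.3% (26.6 to 30.1), monocyte-like at 20.4% (18.9 to 22.0) and granulocyte-monocyte progenitor-like cells at 15.5% (14.1 to 16.9). The stem or progenitor-like share ranged from 16.1 to 34.9% under other settings. Of the 531 monocyte-like cells there, 393 lay in cluster 8. That cluster had 7 monocyte and 6 granulocyte-monocyte progenitor markers, with 4 of each among its 10 leading genes, so its name is a close call. Lin-CD45- marrow was 91.0% (89.0 to 92.8) erythroid-like. Crushed Lin-CD45-CD71- marrow held LepR-like stromal cells, the leptin receptor-positive perivascular cells of marrow, at 30.7% (28.0 to 33.6), B progenitor-like cells at 25.4% (22.8 to 28.2), fibroblast-like cells at 12.5% (10.6 to 14.6) and osteoblast-like cells at 10.9% (9.07 to 12.9). Bone chips held fibroblast-like cells at 44.1% (41.7 to 46.4) and cells resembling muscle satellite cells at 25.4% (23.3 to 27.5). Undigested flushed marrow held LepR-like and haematopoietic-like cells at 42.4% (38.4 to 46.4) each, and digested flushed marrow held LepR-like cells at 50.1% (47.7 to 52.4) and sinusoidal endothelial-like cells at 32.7% (30.5 to 34.9). The undigested shares depend on the cell filter, at 3.83% and 88.0% with at least 1000 genes and under 5% mitochondrial UMIs required.

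**Figure D2:**
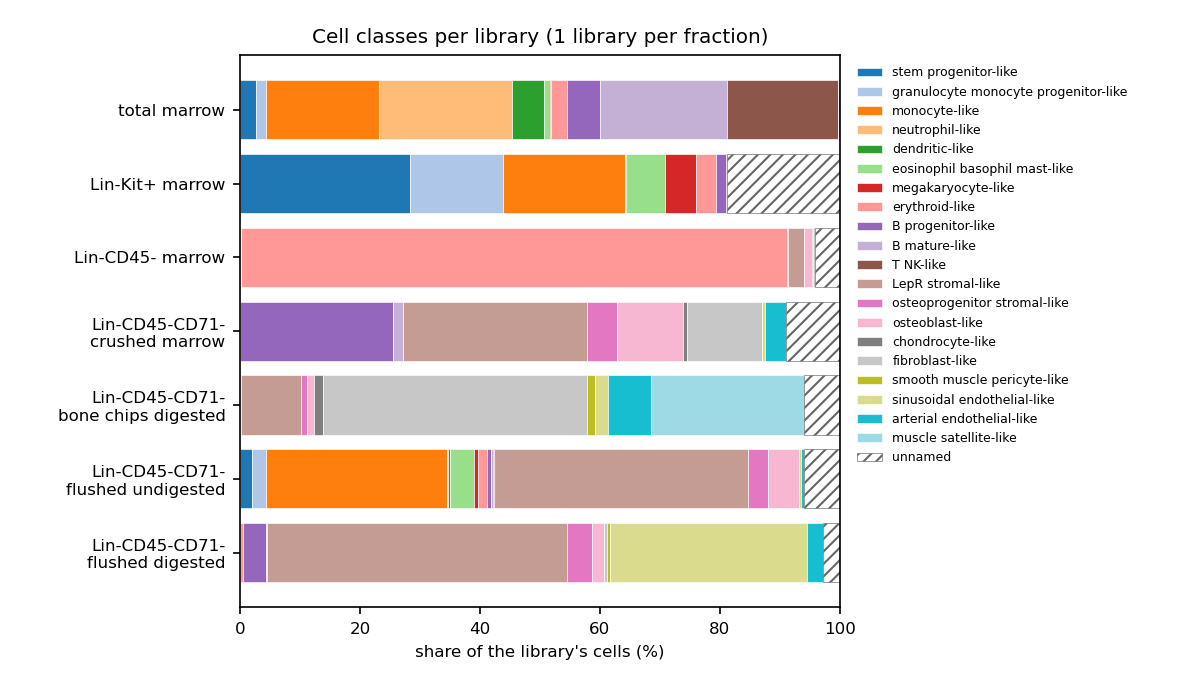
Share of each library's cells, in percent on the x axis, that fell in each cell class, as stacked bars for the 7 libraries, with hatched white for clusters that no marker list named. Erythroid-like cells fill 91.0% of Lin-CD45- marrow, fibroblast-like cells 44.1% of bone chips, and sinusoidal endothelial-like cells 32.7% of digested flushed marrow.

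Lin-Kit+ cells were set against total marrow to see what the progenitor sort enriched. Genes of granule-forming, megakaryocytic and basophil or mast progenitors were more abundant in the Lin-Kit+ library, and genes of mature neutrophils, lymphocytes and red cells were more abundant in total marrow. Prg2, the major basic protein of eosinophil granules, was 126-fold (70.6 to 253) higher in Lin-Kit+ cells, and Cpa3, a mast cell and basophil protease, was 7.29-fold (6.32 to 8.44) higher. Itga2b, the platelet integrin, was 11.6-fold (8.48 to 16.2) higher, Pf4, a platelet chemokine, 9.60-fold (8.31 to 11.1), and Mpl, the thrombopoietin receptor, 18.3-fold (8.80 to 46.0). Camp, a neutrophil granule peptide, was 568-fold (512 to 632) lower, and S100a9, an abundant neutrophil calcium-binding protein, 534-fold (490.2 to 584) lower.

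Of the granulocyte-monocyte progenitor markers, 8 of 8 were at least 2-fold higher in Lin-Kit+ cells, with a median log2 ratio of 1.91. They included Mpo, myeloperoxidase, at 5.01-fold (4.92 to 5.09) and Elane, neutrophil elastase, at 4.03-fold (3.96 to 4.10). Stem and progenitor markers were at least 2-fold higher in 8 of 10 cases (median 1.60, floor value 2.01), among them Cd34 at 6.84-fold (6.12 to 7.66). Megakaryocyte markers were at least 2-fold higher in 5 of 8 cases (median 1.68, floor value 2.35), and eosinophil, basophil and mast cell markers in 5 of 10 (median 1.31). Neutrophil markers were at least 2-fold lower in 10 of 10 cases (median -7.75, floor value -8.60), mature B markers in 6 of 6 (median -4.35), T cell markers in 8 of 8 (median -4.37) and haemoglobin genes in 5 of 7 (median -4.89). Ms4a1, which encodes CD20 of B cells, had 0 against 699 UMIs and was at least 559-fold lower. Of the cell cycle genes, 1 of 14 were at least 2-fold higher and 0 lower.

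Immediate early genes, which are transcribed within minutes of a stimulus, were at least 2-fold lower in Lin-Kit+ cells in 15 of 24 cases and higher in 1, with a median of -1.25 at percentile 0. Klf2, a quiescence factor of lymphocytes on that list, was 29.9-fold (28.1 to 31.7) lower, and Myc was 3.17-fold (2.90 to 3.48) higher. Within monocyte-like cells the list was lower in 22 of 24 cases (median -2.68), with Fos at 17.4-fold (16.3 to 18.4) lower and Atf3, a stress-induced transcription factor, at 87.7-fold (61.1 to 131) lower. Elane was 7.15-fold (6.88 to 7.42) higher in the monocyte-like cells of the Lin-Kit+ sort. Cluster 8 held 74.0% of these cells in Lin-Kit+ and cluster 20 held 89.9% in total marrow, and 18.8% of Lin-Kit+ cells lay in cluster 4, which no marker list named. The stem or progenitor-like share of Lin-Kit+ cells, 28.3%, ranged from 16.1 to 34.9% under other cell filters, clusterings and denominators. The median log2 ratio of all genes was 0.21 by CPM and 0.09 after TMM scaling (trimmed mean of M values). The cell name prefix differed between these libraries, so fraction and run cannot be told apart.

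Lin-CD45- cells, from which most white cells had been removed, were set against total marrow. Red cell, cell cycle and bone matrix genes were more abundant in them, and neutrophil and monocyte genes in total marrow. Erythroid-like cells were 91.0% (89.0 to 92.8) of Lin-CD45- cells and 2.67% (1.82 to 3.77) of total marrow, and mesenchymal-like cells were 4.44% (3.22 to 5.95) and 0.172% (0.0209 to 0.621). Gypa, which encodes glycophorin A of the red cell membrane, was 14.9-fold (13.8 to 16.0) higher in Lin-CD45- cells, Hba-a1, an alpha globin, 10.2-fold (9.99 to 10.4), and Klf1, the master transcription factor of erythroid cells, 11.6-fold (10.6 to 12.7). Mgp, the matrix Gla protein of bone and cartilage, was 62.8-fold (24.4 to 231) higher. S100a8, the partner of S100a9, was 20756-fold (14779 to 30154) lower, and Lyz2, lysozyme of myeloid cells, was 8889-fold (6109 to 13489) lower. The prefix was shared, and median depth was 24136 UMIs per cell against 5168.

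Haemoglobin genes were at least 2-fold higher in Lin-CD45- cells in 7 of 7 cases (median log2 ratio 3.18), as were 8 of 8 erythroid progenitor markers (median 3.15) and 8 of 8 erythroblast markers (median 3.18), among them Car2, a red cell carbonic anhydrase, at 9.60-fold (9.41 to 9.80). Cell cycle genes were higher in 11 of 14 cases (median 1.41), including Mki67, a marker of cycling cells, at 3.57-fold (3.30 to 3.87) and Rrm2, which makes deoxyribonucleotides, at 3.18-fold (3.07 to 3.29). Collagen and matrix genes were higher in 17 of 20 cases and lower in 1 (median 1.75, floor value 3.01), with Sparc, a bone matrix glycoprotein, at 18.3-fold (12.3 to 28.7) and Col1a1, a chain of type I collagen, at 13.3-fold (9.61 to 19.0). LepR-like stromal markers were higher in 6 of 10 cases (median 1.12) and osteoblast markers in 6 of 10 (median 1.22), with Bglap, osteocalcin, at 16.6-fold (11.3 to 25.5). Cxcl12, the chemokine that retains stem cells in marrow, was 5.01-fold (4.27 to 5.93) higher. Immediate early genes were lower in 24 of 25 cases (median -4.19, floor value -5.27), with Fos at 142-fold (128 to 158) lower. Neutrophil markers were lower in 10 of 10 cases (median -10.43, floor value -13.45) and monocyte markers in 9 of 9 (median -6.83). Over all genes the median log2 ratio was -0.16 by CPM and 0.05 after TMM scaling.

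Crushed Lin-CD45-CD71- marrow was set against Lin-CD45- marrow for what the CD71 gate leaves. Stromal, bone and B progenitor genes were more abundant in it, and red cell and cell cycle genes in Lin-CD45- marrow. Erythroid-like cells were 0 of 1057 cells, which allows a share of up to 0.284%, against 91.0%. LepR-like cells were 30.7% (28.0 to 33.6) against 2.64% (1.72 to 3.88), osteoblast-like cells 10.9% (9.07 to 12.9) against 1.27% (0.657 to 2.21), and B progenitor-like cells 25.4%. Plp1, the main protein of central myelin, was 5054-fold (3272 to 8277) higher in crushed cells, Apod, a lipid carrier, 1269-fold (780.1 to 2222), and Cxcl12 75.6-fold (72.3 to 79.0). Msmp, a secreted protein, had 3853 against 0 UMIs and was at least 7502-fold higher. Gypa was 833-fold (383 to 2269) lower and Hba-a1 479-fold (386 to 601) lower.

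Haemoglobin genes were at least 2-fold lower in 7 of 7 cases (median log2 ratio -7.19) and cell cycle genes in 14 of 14 (median -3.78), with Birc5, survivin, at 30.6-fold (25.9 to 36.6) lower. Collagen and matrix genes were higher in 20 of 21 cases (median 5.65), among them Dcn, decorin, at 246-fold (221 to 276) and Col1a1 at 122-fold (115 to 129). Matrix enzymes were higher in 14 of 14 (median 5.34), with Mmp13, a collagenase of bone, at 83.5-fold (76.8 to 90.8). Niche cytokines were higher in 16 of 16 (median 4.80), niche growth factors in 19 of 19 (median 4.32) and niche adhesion and Notch ligand genes in 10 of 11 (median 4.10), with Vcam1, a vascular adhesion molecule, at 52.1-fold (45.3 to 60.1). B progenitor markers were higher in 9 of 9 (median 6.72), with Igll1 of the surrogate light chain at 565-fold (418 to 786). LepR-like stromal, osteoblast and fibroblast markers were each higher in 10 of 10 cases (medians 5.70, 6.37 and 5.55). Immediate early genes were higher in 25 of 25 (median 6.04), with Fos at 347-fold (312 to 386), and heat shock genes had a median of 0.62, with 4 of 12 higher and 3 lower, and were lower on balance after TMM scaling. Prefix, sort medium (lysis buffer for the crushed cells per the labels, saline with serum for the others) and depth differed between these libraries and cannot be told apart from the CD71 gate. Over all genes the median log2 ratio was 0.73 by CPM and -0.17 after TMM scaling.

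Cells digested from bone fragments were set against crushed marrow cells of the same gate and prefix, so that anatomical site, digestion and sort medium differed together. Fibroblast, muscle and endothelial genes were more abundant in bone chips, and B progenitor, osteoblast and LepR-like stromal genes in crushed marrow. Fibroblast-like cells were 44.1% (41.7 to 46.4) of chip cells against 12.5% (10.6 to 14.6), arterial endothelial-like cells 7.21% (6.04 to 8.53) against 3.41% (2.40 to 4.68), and LepR-like cells 9.92% (8.55 to 11.4) against 30.7% (28.0 to 33.6). Of the 36 arterial endothelial-like cells of crushed marrow, 17 held a UMI of Ccl21a, a chemokine of lymphatic vessels chosen after its values were seen, against 0 of 125 in chips. B progenitor-like cells were 0 of 1734 chip cells, which allows a share of up to 0.173%, against 25.4%. Acta2, smooth muscle actin, was 103-fold (53.9 to 225) higher in chips and Myod1, a muscle-determining factor, at least 84.4-fold higher. Vpreb1, a pre-B cell receptor chain, was 693-fold (365 to 1517) lower and Igll1 at least 1974-fold lower.

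Muscle satellite markers were at least 2-fold higher in chips in 7 of 7 cases (median log2 ratio 4.81), with Chodl, a lectin of satellite cells, at 124-fold (48.4 to 458). Fibroblast markers were higher in 9 of 10 (median 1.94), including Dpt, dermatopontin, at 9.57-fold (8.33 to 11.0) and Dcn at 3.87-fold (3.8 to 3.94). Tendon and endosteal fibroblast markers were higher in 7 of 8 (median 1.79), chondrocyte markers in 7 of 10 (median 1.65) and arterial markers in 8 of 12 (median 1.51), with Sox17, an arterial transcription factor, at 21.4-fold (11.1 to 47.2). Osteoblast markers were lower in 10 of 10 (median -2.58), with Bglap at 9.20-fold (8.93 to 9.48) lower, LepR-like stromal markers in 8 of 10 (median -1.40), and B progenitor markers in 9 of 9 (median -6.84, floor value -7.77). Cell cycle genes were lower in 13 of 14 (median -2.11). Collagen and matrix genes were higher in 7 of 21 and lower in 2 (median 0.61), with Fn1, fibronectin, at 3.92-fold (3.66 to 4.20) higher and Col1a2 at 2.16-fold (2.11 to 2.21) lower. Matrix enzymes were higher in 8 of 15 and lower in 2 (median 1.19), with Mmp3, stromelysin, at 12.8-fold (8.42 to 20.4) higher and Mmp13 at 5.56-fold (5.30 to 5.82) lower. Niche cytokines were higher in 5 of 16 and lower in 6, with the monocyte attractant Ccl2 at 6.38-fold (5.90 to 6.91) higher and Cxcl12 at 2.98-fold (2.92 to 3.04) lower. Neutrophil markers were also higher in 6 of 7 (median 3.89), although 3 of 1734 chip cells were haematopoietic-like, all of them neutrophil-like. The median log2 ratio of all genes was -0.20 by CPM and 0.02 after TMM scaling.

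Within LepR-like cells, immediate early genes were at least 2-fold higher in chips in 11 of 25 cases and lower in 0 (median 0.82, percentile 100), and heat shock genes in 6 of 12 (median 1.0). Tnfrsf12a, a receptor induced on injury, was 9.97-fold (5.29 to 20.4) higher, Il6, an inflammatory cytokine, 7.11-fold (4.15 to 12.8), Myc 4.97-fold (3.98 to 6.24) and Hspa1a, the inducible heat shock protein, 4.78-fold (4.08 to 5.61). Cxcl12 stood at 26425 against 26105 CPM in chip and crushed LepR-like cells. Collagen and matrix genes had a median of -0.25, with 3 of 20 higher. Within fibroblast-like cells, Ccl2 was 12-fold (9.43 to 15.4) higher in chips, Msmp was 2290.2-fold (1110 to 5702) lower and Cxcl12 7.96-fold (6.77 to 9.36) lower. Matrix enzymes were higher there in 5 of 14 (median 0.39). The median log2 ratio of all genes was -0.21 by CPM and -0.03 after TMM scaling in LepR-like cells, and -0.10 and 0.10 in fibroblast-like cells.

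The flushed pair addressed what enzymatic digestion does to the yield from 1 kind of marrow preparation. Endothelial genes were far more abundant in the digested library, and myeloid and basophil progenitor genes far more abundant in the undigested one. Sinusoidal endothelial-like cells were 32.7% (30.5 to 34.9) of digested and 0.328% (0.0398 to 1.18) of undigested cells, and haematopoietic-like cells were 4.46% (3.55 to 5.52) and 42.4% (38.4 to 46.4). Plvap, a protein of fenestrated endothelium, was 156-fold (66.7 to 481) higher in digested cells, Fabp4, a fatty acid carrier of small vessels, 167-fold (114 to 253), and Lrg1, a vascular glycoprotein, 131-fold (73.0 to 262). Lyz2 was 1163-fold (649 to 2331) lower, and Mcpt8, a basophil protease, with 0 against 2563 UMIs, was at least 2532-fold lower.

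Sinusoidal endothelial markers were at least 2-fold higher in digested cells in 8 of 9 cases (median log2 ratio 4.99, floor value 5.38), arterial markers in 6 of 7 (median 2.59), and LepR-like stromal markers in 7 of 10 (median 1.19). Niche adhesion genes were higher in 13 of 15 (median 2.57), niche growth factors in 15 of 21 (median 1.31) and niche cytokines in 11 of 17 (median 1.52, floor value 1.19), with Vcam1 at 4.33-fold (3.97 to 4.73) and Cxcl12 at 2.87-fold (2.81 to 2.94). Collagen and matrix genes were higher in 12 of 21 (median 1.19) and matrix enzymes in 11 of 13 (median 1.47). Granulocyte-monocyte progenitor markers were lower in 7 of 8 (median -7.29), monocyte markers in 6 of 9 (median -5.07), eosinophil, basophil and mast cell markers in 6 of 7 (median -6.37) and cell cycle genes in 14 of 14 (median -2.29). With at least 1000 genes and under 5% mitochondrial UMIs required, the LepR-like share of undigested cells was 3.83% in place of 42.4%, the haematopoietic-like share 88.0%, and 0 sinusoidal endothelial-like cells were left. The undigested cells were shallow, with a median of 781 genes against 1050.

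Immediate early genes were higher in the digested library in 25 of 25 cases (median 2.73). Within LepR-like cells they were at least 2-fold higher in 22 of 25 and lower in 0, with a median log2 ratio of 2.21 (counting interval 2.10 to 2.44) at percentile 100. Fos stood at 11430 against 1489.7 CPM in digested and undigested LepR-like cells, 7.67-fold (6.96 to 8.48) higher, and Cyr61, a matricellular protein of the list, was 6.29-fold (5.60 to 7.08) higher. Atf3, with 181 against 0 UMIs, was at least 7.95-fold higher, and Rhob, a small GTPase, stood at 161 against 178 CPM. Heat shock genes were higher in 6 of 12 (median 1.14), with Hspa1a at 12.5-fold (9.22 to 17.5). The chemokines Ccl2 and Cxcl1 were 9.15-fold (7.08 to 12) and 26.2-fold (10.2 to 96.5) higher, and Ccl19, which attracts lymphocytes, was 2.34-fold (1.93 to 2.83) lower. Vegfa, the main angiogenic factor, was 3.01-fold (2.3 to 3.92) lower and Cdkn1b, a cell cycle inhibitor, 5.36-fold (3.62 to 7.87) lower. Cxcl12 stood at 28131 against 24904 CPM. Niche adhesion genes had a median of 0.08, or -0.20 with genes at 0 UMIs at the floor, and collagen and matrix genes one of -0.31, with 2 of 19 higher and 3 lower, that was near 0 after TMM scaling. Haemoglobin genes, read here as free RNA, had a median of 1.72. Different clusters held the class, cluster 0 with 91.5% of digested and cluster 10 with 96.9% of undigested LepR-like cells, and with cluster 10 alone the immediate early median was 0.78. Cluster 10 also held 24 of the 25 LepR-like cells of Lin-CD45- marrow, which had a median of 5088 UMIs, so its cells were not all shallow. Immediate early genes were not kept out of the clustering. The median mitochondrial share of UMIs was 1.54% in digested and 2.38% in undigested LepR-like cells. The median log2 ratio of all genes in LepR-like cells was -0.15 by CPM and 0.16 after TMM scaling.

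**Figure D3:**
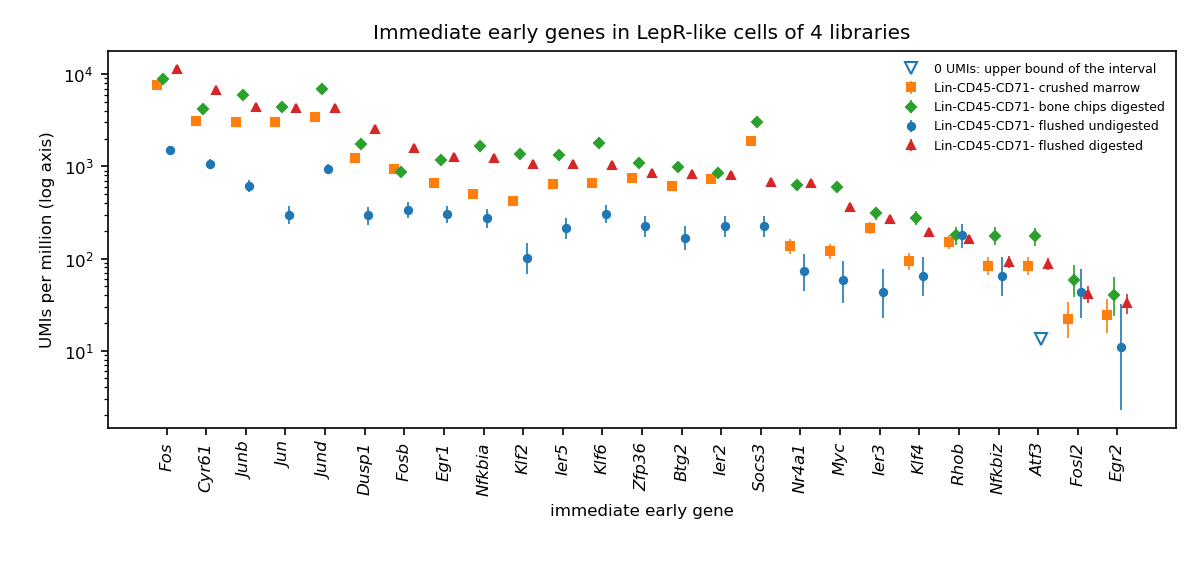
The 25 immediate early genes on the x axis and their level in LepR-like cells on a log y axis, in CPM, for crushed, bone chip, undigested flushed and digested flushed libraries, with bars for exact Poisson 95% intervals and an open triangle for the upper bound of Atf3 at 0 UMIs in undigested cells. The median over the list was 644 CPM in crushed, 1085 in chip, 225 in undigested and 846 in digested cells.

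Undigested flushed marrow against undigested crushed marrow addressed how the marrow was taken out. Myeloid and basophil progenitor genes were more abundant in flushed marrow, and B progenitor, osteoblast and fibroblast genes in crushed marrow. Haematopoietic-like cells were 42.4% (38.4 to 46.4) of flushed cells and 27.2% (24.5 to 29.9) of crushed cells, where 269 of the 287 were B progenitor-like. With at least 1000 genes and under 5% mitochondrial UMIs required, the flushed share was 88.0%. Fibroblast-like cells were 0 of 609 flushed cells, which allows a share of up to 0.493%, against 12.5% (10.6 to 14.6). Mpo was 1389.7-fold (595 to 4284) higher in flushed cells and Ly6c2 153-fold (103 to 237), and Elane, with 3838 against 0 UMIs, was at least 3935-fold higher. Bglap was 18.0-fold (16.6 to 19.6) lower, Igll1 52.9-fold (35.8 to 81.8) and Dcn 23.3-fold (20.2 to 27.0).

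Granulocyte-monocyte progenitor markers were at least 2-fold higher in flushed marrow in 7 of 8 cases (median log2 ratio 7.78), monocyte markers in 7 of 9 (median 4.26), eosinophil, basophil and mast cell markers in 7 of 7 (median 6.37), haemoglobin genes in 4 of 6 (median 3.18) and cell cycle genes in 12 of 14 (median 1.87). B progenitor markers were lower in 9 of 9 (median -3.71, floor value -3.25), fibroblast markers in 5 of 7 (median -4.90), osteoblast markers in 7 of 10 (median -2.69) and collagen and matrix genes in 14 of 21 (median -1.2). Of the LepR-like stromal markers, 0 of 10 were higher and 1 lower. Immediate early genes were lower in 19 of 25 and higher in 1 (median -1.80). Within LepR-like cells they were lower in 19 of 25 (median -1.58), with Fos at 5.15-fold (4.66 to 5.70) lower. Pam, a peptide-amidating enzyme, was 7.26-fold (6.2 to 8.53) higher in flushed LepR-like cells, Notch2, a Notch receptor, 6.56-fold (5.18 to 8.35), Vegfa 3.70-fold (2.67 to 5.13) and Kitl, stem cell factor, 2.29-fold (1.99 to 2.63). Cxcl12 stood at 24904 against 26105 CPM. Cluster 10 held 96.9% of flushed and cluster 0 held 93.5% of crushed LepR-like cells, whose median log2 ratio of all genes was 0.06 by CPM and -0.17 after TMM scaling. Prefix, sort medium and depth differed between these libraries and cannot be told apart from the way of taking marrow.

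Bone chips against digested flushed marrow compared both digested preparations. Fibroblast and matrix genes were more abundant in chips, and sinusoidal endothelial, LepR-like stromal and red cell genes in flushed marrow. Fibroblast-like cells were 44.1% (41.7 to 46.4) of chip cells and 0.446% (0.193 to 0.877) of flushed cells, sinusoidal endothelial-like cells 2.25% (1.60 to 3.06) and 32.7% (30.5 to 34.9), and LepR-like cells 9.92% (8.55 to 11.4) and 50.1% (47.7 to 52.4). Mfap5, a microfibril protein of fibroblasts, was 603-fold (359 to 1103) higher in chips, Prg4, the joint lubricin, 223-fold (113 to 516), and Cd34 47.5-fold (37.9 to 60.3). Stab2, a scavenger receptor of sinusoids, was 18.2-fold (14.4 to 23.2) lower, Lepr 9.23-fold (8.33 to 10.3) and Il7, a lymphocyte growth factor, 11.0-fold (8.74 to 14.0).

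Fibroblast markers were at least 2-fold higher in chips in 6 of 7 cases (median log2 ratio 5.48), collagen and matrix genes in 11 of 21 (median 1.2) and matrix enzymes in 6 of 14, with 3 lower (median 0.52). Sinusoidal markers were lower in 8 of 9 (median -2.96), LepR-like stromal markers in 10 of 10 (median -2.51), niche cytokines in 10 of 17 (median -1.50), niche growth factors in 11 of 20 (median -1.30), niche adhesion genes in 8 of 15 (median -1.14) and haemoglobin genes in 6 of 7 (median -6.78). Cxcl12 was 7.25-fold (7.12 to 7.39) lower over the whole library and stood at 26425 against 28131 CPM within LepR-like cells. Immediate early genes had a median of -0.21 over the whole library, which turned positive after TMM scaling, and 0.31 within LepR-like cells, where 1 of 25 were at least 2-fold higher. In those cells Il6 was 71.0-fold (26.3 to 269) higher in chips, Rgs16, a regulator of G protein signalling, 12.3-fold (9.54 to 16.1) and Socs3, a feedback inhibitor of cytokine signalling, 4.57-fold (4.24 to 4.92), while Il7 was 2.11-fold (1.60 to 2.83) lower. All genes had a median log2 ratio of -0.29 by CPM and 0.04 after TMM scaling, and -0.21 and -0.08 within LepR-like cells. Prefix and site differed together and cannot be told apart.

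Mesenchymal and endothelial cells were compared for 57 niche genes, which encode signals that maintain blood-forming cells, across the 3 libraries with at least 20 cells of both. These were crushed marrow (633 and 41 cells), bone chips (1022 and 164) and digested flushed marrow (1027 and 635). Of 51 testable genes, 25 were higher in mesenchymal and 12 in endothelial cells, adjusted over the list alone, and 14 did not pass. Adjusted over all 10064 genes tested, the counts were 20 and 11. Cxcl12 was higher in mesenchymal cells, with a log2 fold change of 5.29 ± 0.81 (approximate SE from the F statistic, edgeR quasi-likelihood test with library as a block, Benjamini-Hochberg adjusted p over the list alone 0.000183, higher in 3 of 3 libraries). Csf1, the macrophage growth factor, was higher by 3.04 ± 0.36 on the log2 scale (edgeR adjusted p 3.07e-05, 3 of 3), and Ccl19 by 7.92 ± 0.58 (edgeR adjusted p 1.11e-06, 3 of 3, with 1 endothelial UMI against 1265). The mesenchymal sums mix classes with very different Cxcl12 levels. In chips these were 26425 CPM in LepR-like, 84.4 in fibroblast-like and 0 in osteoblast-like cells. Arterial and sinusoidal endothelial-like cells there stood at 231.5 and 546 CPM. In digested flushed marrow osteoblast-like cells stood at 905 and sinusoidal ones at 659 CPM. Low counts of Cxcl12 were absent from crushed and chip cells, where the smallest count above 0 was 5 and 3 UMIs. Low Cxcl12 levels in those libraries, the 0 included, may therefore be too low, and the fold change may be affected.

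Of the 16 cytokines tested, 10 were higher in mesenchymal cells and 0 in endothelial cells. Of 20 growth factors, 12 were higher in mesenchymal and 2 in endothelial cells, and of 15 adhesion and Notch ligand genes, 3 and 10. Endothelial cells had higher Dll4, a Notch ligand (log2 fold change -6.87 ± 0.46), Icam2, an endothelial adhesion molecule (-6.44 ± 0.37), the junction protein Esam (-7.05 ± 0.48), and the selectins Sele (-7.05 ± 0.63) and Selp (-6.86 ± 0.47), each in 3 of 3 libraries. In crushed marrow the selectin direction rests on 2 endothelial UMIs of Sele and 1 of Selp against 0 in mesenchymal cells, and without digested flushed marrow the values were -8.41 and -7.68. Of its 41 endothelial cells, 36 were the arterial endothelial-like ones that included cells with Ccl21a. In mesenchymal cells Cd44, the hyaluronan receptor, was higher by 5.60 ± 0.72, with 1 endothelial UMI against 428. Tnfsf13b, the B cell survival factor BAFF, was higher by 7.09 ± 1.71, with 0 endothelial UMIs against 79, at least 4.61-fold. Fitted values and the approximate SE of such scarce genes depend on the prior count.

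Kitl passed over the list alone, at 2.36 ± 0.90 (edgeR adjusted p 0.0383, and 0.113 over all genes), and was higher in mesenchymal cells in 2 of 3 libraries. In chips it stood at 67.9 CPM in mesenchymal and 114.9 CPM in endothelial cells. By class, Kitl there stood at 497 CPM in LepR-like and 7.61 in fibroblast-like cells, and at 146 in arterial and 21.0 in sinusoidal endothelial-like cells. Its call was lost without crushed marrow (log2 fold change 1.89, edgeR adjusted p 0.269) and without digested flushed marrow (0.80, 0.375), and it stood at 4.20 without chips. Il7 was higher by 3.57 ± 0.71 (edgeR adjusted p 0.00113, 3 of 3 libraries) and missed the threshold without digested flushed marrow (1.92, edgeR adjusted p 0.0514), with 4.72 without crushed marrow. Vcam1, at 1.04 ± 0.52, did not pass (edgeR adjusted p 0.0951), passed without chips (1.54, edgeR adjusted p 0.00997) and with no filter on low counts (1.09, edgeR adjusted p 0.0261), and stood at 0.31 without crushed marrow. The Cxcl12 value ranged from 4.40 without crushed marrow to 6.27 without chips, the Ccl19 value up to 10.39 without digested flushed marrow and the Cd44 value up to 7.69 without chips. The number of calls ranged from 21 to 31 for mesenchymal and 11 to 13 for endothelial cells when 1 library was left out. The 3 libraries are different preparations, so the spread is between preparations, with 2 residual degrees of freedom.

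**Figure D4:**
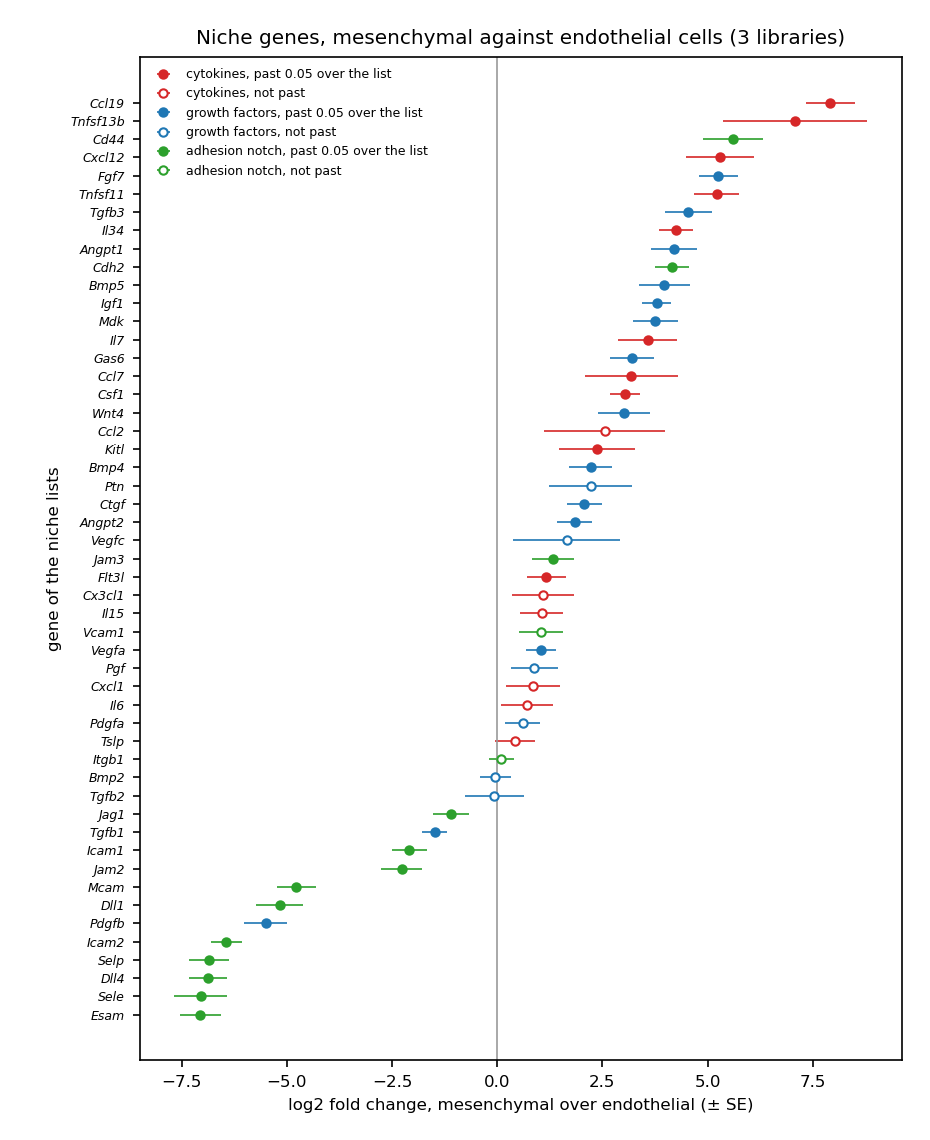
Log2 fold change of 51 niche genes, mesenchymal over endothelial cells, with its approximate standard error (from the F statistic), from 3 libraries, with filled points past an adjusted p of 0.05 over the list alone and colours for cytokines, growth factors and adhesion or Notch ligand genes. Values to the right, such as Cxcl12 at 5.29, are higher in mesenchymal cells and values to the left, such as Dll4 at -6.87, in endothelial cells, and fitted values of genes with 0 or 1 endothelial UMI depend on the prior count.

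LepR-like and fibroblast-like cells met in 2 libraries, crushed marrow (325 and 132 cells) and bone chips (172 and 764), which is too few for a test. Niche genes had been kept out of the clustering, and none of them named a class. Of 37 niche genes compared in both, 20 were at least 2-fold higher in LepR-like cells in both libraries and 1, Cd44, in fibroblast-like cells, which was chosen after its values were seen. Cxcl12 was 38.9-fold (35.0 to 43.3) higher in LepR-like cells of crushed marrow and 313-fold (277 to 355) higher in those of chips. Both libraries lacked low counts of Cxcl12, so these folds may be too large, which their intervals do not cover. Kitl was 72.4-fold (28.1 to 267) and 65.3-fold (42.8 to 104) higher. Sinusoidal and arterial endothelial-like cells met in bone chips (39 and 125 cells) and digested flushed marrow (586 and 49). Of 15 niche genes, Vcam1 and, chosen after their values were seen, Cxcl1, Icam1 and Selp were at least 2-fold higher in sinusoidal cells in both libraries. Kitl was higher in arterial cells of both. Vcam1 stood at 768 against 143 CPM in chips and 1677 against 258 CPM in digested flushed marrow.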

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

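The tests in this part were chosen after the results were seen, apart from thinning to 1000 UMIs, which was fixed before the data were examined. A cluster led by the myelin genes Plp1 and Mbp held 6.05% of crushed Lin-CD45-CD71- cells and 1.44% of bone chip cells (64 and 25 cells), and was left unnamed after its leading genes were seen, although Cnp, Mbp and Plp1, which both kinds of myelin express, gave it 3 markers of the Schwann cell list. Peripheral glia are argued against by Mpz, the main peripheral myelin transcript, seen in 0 of 89 cells, which allows up to 3.37% of cells with a UMI of it (a limit on detection, not on expression; bone chips held 23 UMIs of it in muscle satellite-like cells), and no more than 2 of 8 peripheral myelin genes (Pmp22, also in 29.6% of other crushed cells, and Sox10, also on the central list) were seen in over 50% of its cells. Free RNA is not decided by 7 central myelin genes outside the 10 leading ones. These were seen at the median in 2.22% of other crushed cells (median 2826 UMIs) against 87.6% of the cluster's cells (median 6903 UMIs). Myelin genes were not kept out of the clustering, so a difference in this direction was built in. Low counts of Plp1, Mbp and Aplp1 were also absent from crushed marrow, so a background in other cells could be missing. That 87.6%, with 10 of 12 central myelin genes in over 50% of the cells and 0 of 3 other neural genes, leaves central nervous tissue taken along with the bone as a candidate source. The design names no group that gives a biological explanation, so none was tested beyond these cell identities, and whether such cells belong to marrow stays open.

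Haematopoietic-like cells made up 42.4% of undigested flushed cells although the sort excluded CD45-positive and lineage-positive cells. Their share was 88.0% with at least 1000 genes and under 5% mitochondrial UMIs required. Free RNA as the whole cause is not decided by Ptprc, the CD45 gene, which named no class. It had 81 UMIs in monocyte-like cells (median depth 2902.5 UMIs) and 3 in LepR-like cells (median 1025 UMIs) of the same library, a ratio of 13 (counting interval 4.29 to 64.2). Ptprc was not kept out of the clustering that set these classes apart, so a difference in this direction was partly built in. In the monocyte-like cells Ptprc stood at 141 CPM against 171 CPM in monocyte-like cells of total marrow, a ratio of 0.825 (0.641 to 1.05). Carry-over of cells with ordinary CD45 transcript levels remains a candidate explanation, with the limit that the class lay mostly in different clusters, cluster 12 with 89.7% of the undigested flushed and cluster 20 with 89.9% of the total marrow cells. Surface protein was not measured, so loss of the antigens in handling stays open, and no biological explanation was tested.

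Immediate early genes were higher in digested than in undigested LepR-like cells, with a median log2 ratio of 2.21. With cells thinned to 1000 UMIs the median was 2.05. Random thinning leaves expected CPM unchanged apart from weighting cells equally. It also drops cells under 1000 UMIs, where the undigested LepR-like cells had a median of 1025. It therefore cannot decide whether depth plays a part. Loss of cytoplasm in the undigested cells goes with the direction of the nuclear transcripts Malat1, Neat1, Kcnq1ot1 and Gm26917, all 4 higher there. It also goes with a median mitochondrial share of 2.38% against 1.54%. The median of these transcripts was -0.54 (-0.82 to -0.17). How large it would have to be to give the whole pattern is not known, so loss of cytoplasm stays open as a cause, in whole or in part. The digestion itself cannot be told apart from other handling, because undigested LepR-like cells of crushed marrow, with another prefix and sort medium, were higher than undigested flushed ones (median -1.58 for flushed over crushed). Cluster 10 also held 24 of the 25 LepR-like cells of Lin-CD45- marrow (median 5088 UMIs), from the liquid of crushed bones. Immediate early levels of those few cells were not compared. Restricted to cluster 10, the median of digested over undigested flushed cells was 0.78, but immediate early genes were not kept out of the clustering. Which LepR-like cells each library held therefore stays open, and a response of living cells to the enzymes is untested.

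Other unnamed clusters held a share above what 3 cells would give. Cluster 4 held 18.8% of Lin-Kit+ cells and was led by Gm15915, Car1, Sdsl and Mfsd2b. Cluster 24 held 4.15% of bone chip cells and was led by Apod, Angptl7 and Gpc3. Cluster 26 held 1.78% of digested flushed cells and was led by Cxcl9, Cxcl10 and Ifit1. Cluster 27 held 1.89% of crushed cells and was led by Mepe, Dmp1, Spp1 and Col10a1, a matrix collagen of cartilage that is being replaced by bone. It had 3 chondrocyte markers, Acan, Hapln1 and Sox9, but 0 of them among its 10 leading genes, which held 1 osteoblast marker. These leading genes were chosen after their values were seen.

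For 3 niche genes the mesenchymal over endothelial ratio was beyond 2-fold by its whole counting interval in opposite directions in different libraries, a difference that was not tested. Other niche genes, Ptn, Ccl7 and Kitl among them, also differed in sign between libraries without meeting that bound. Ccl2 stood at -2.87 in crushed marrow, 4.83 in bone chips and 3.60 in digested flushed marrow. Vegfc, a lymphatic growth factor, stood at 2.01 in crushed marrow with its 0 endothelial UMIs set to the floor, -2.24 in chips and 4.24 in digested flushed marrow. Tgfb2 stood at -2.75 in crushed marrow (33 against 10 UMIs), -0.26 in chips and 2.06 in digested flushed marrow. These genes, Ptn and Ccl7 were chosen after their values were seen.

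For the niche test, the 6 sums of 3 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 37 niche genes, the highest other split 0, and 1 of 10 splits called as many. Each other split put sums of both cell groups on both sides, so their difference became residual spread. Few calls were likely there whatever the data, and no conclusion is drawn from the counts.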

How the results depend on the processing

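The 5% mitochondrial limit alone, the removal of high Scrublet scores, cluster 10 alone, the denominator without unnamed clusters and the omission of genes with absent low counts were chosen after seeing the data. Of 160 values of main results under alternatives, 118 stayed within their counting interval, or for counts within 1.5-fold, and 42 moved. Most of these values are shares or counts, which cannot change sign, and the list medians among them kept theirs. The cause was not tested for any of these moves except where given.

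The erythroid-like share of Lin-CD45- cells (91.0%) was 95.2% with no cell filter, with at least 1000 genes and under 5% mitochondrial UMIs, with under 5% mitochondrial UMIs, with the joint table's cells, at resolution 2, with 1000 variable genes and with niche genes used. It was 95% with high Scrublet scores removed and with unnamed clusters left out. In crushed Lin-CD45-CD71- marrow it was 0.378% with 1000 variable genes.

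The stem or progenitor-like share of Lin-Kit+ cells (28.3%) was 16.4% with no cell filter and at resolution 2, 16.6% with the joint table's cells and with niche genes used, 16.1% with under 5% mitochondrial UMIs, 17.4% with high Scrublet scores removed, 20.6% with at least 1000 genes and under 5% mitochondrial UMIs, 31.3% with 1000 variable genes and 34.9% with unnamed clusters left out.

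With at least 1000 genes and under 5% mitochondrial UMIs, shares were 67.1% for non-haematopoietic-like cells of crushed marrow (63.9%), 52.9% for fibroblast-like chip cells (44.1%), and in digested flushed marrow 22.9% for sinusoidal (32.7%) and 63.1% for LepR-like cells (50.1%). In undigested flushed marrow they were 0% for sinusoidal (0.328%), 3.83% for LepR-like (42.4%) and 88.0% for haematopoietic-like cells (42.4%). There the filter itself removes the shallow LepR-like cells, whose median was 1025 UMIs against 2902.5 in monocyte-like cells.

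With unnamed clusters left out, shares were 70.2% for non-haematopoietic-like and 33.8% for LepR-like cells of crushed marrow (30.7%) and 46.9% for fibroblast-like chip cells, by a smaller denominator. The last was 41.6% with the joint table's cells, 41.5% at resolution 0.5 and 41.4% with 1000 variable genes. With each cell assigned by its marker UMIs, non-haematopoietic-like cells of crushed marrow were 69.3% and haematopoietic-like cells of undigested flushed marrow 47.8%. The latter were 47.1% with no cell filter and 47.0% with 1000 variable genes and with niche genes used. Sinusoidal cells of digested flushed marrow were 34.9% with niche genes used.

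After TMM scaling, the collagen and matrix median of chips over crushed marrow (0.61) was 0.84. The immediate early median of digested over undigested LepR-like cells (2.21) was 2.52 after TMM scaling, 2.05 with cells thinned to 1000 UMIs and 0.78 with cluster 10 only.

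Other list medians moved in 199 of 706 values. Of 328 values of lists at 2-fold or more, 328 kept their sign and 284 stayed at 2-fold. Single genes moved in 2088 of 6000 values. Of 4440 values of genes at 2-fold or more, 4439 kept their sign and 4268 stayed at 2-fold. The exception, Col9a2, reached 0 in thinned cells.

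Niche calls of 37 genes were shared by 33 under DESeq2, 37 without a low-count filter, 32 without the library block, 33 with at least 50 cells, 37 at resolution 2 and 33 with high Scrublet scores removed, where Sele and Selp gave no value. Without crushed, chip or digested flushed marrow, 33, 35 and 31 were shared. Over these settings 21 to 31 genes were higher in mesenchymal and 9 to 14 in endothelial cells. Left-out libraries gave Kitl 0.80 to 4.20, Il7 1.92 to 4.72, Vcam1 0.31 to 1.54, Cxcl12 4.40 to 6.27 and Csf1 2.57 to 3.35. Adjusted p over the edgeR and DESeq2 settings ranged from 1.37e-13 to 0.375 for Kitl, 2.17e-10 to 0.0514 for Il7 and 0.00997 to 0.547 for Vcam1. Of 115 values of named niche genes, 109 kept their side of the threshold, 4 lost it and 2 gained it. The setting of at least 50 cells and the fit without crushed marrow are the same fit, so 1 lost value is counted again.

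Removal of Scrublet's own doublet calls was not run, since they took 913 of 946 Lin-CD45- cells. Between fractions, no paired analysis was possible because each was 1 library and no label pairs them, while the niche test paired both cell groups within a library through its block. Depth limits the flushed pair most, where 466 undigested and 1693 digested cells reached 1000 UMIs. Simulated 2-fold changes were recovered in 7% of genes by the procedure of the niche test, adjusted over all genes and not over the list alone.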

Other observations

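Levels per class of some genes in stromal and vascular cells are added here, all chosen for this part after their values were seen. Of these, Ccl21a and Msmp also appear in comparisons above. In crushed marrow the 36 arterial endothelial-like cells included cells with Ccl21a, a chemokine of lymphatic vessels, at 19657 CPM (18765 to 20579), against 30.8 CPM (20.6 to 44.2) in LepR-like cells. A UMI of it was seen in 17 of the 36 (47.2%, median depth 2525.5 UMIs) and in 8.92% of LepR-like cells (median 2805 UMIs). Lyve1, a lymphatic and sinusoidal receptor, stood at 602.5 CPM (455 to 782) in them, and both had 0 UMIs in the 125 arterial endothelial-like cells of bone chips. Msmp stood at 5085 CPM (4895 to 5280) in crushed fibroblast-like cells and at 265 to 407 CPM in the other crushed classes and unnamed clusters. Cluster 26 of digested flushed marrow, with 32 cells, had the interferon-induced chemokines Cxcl9 at 2688 CPM (2322 to 3095) and Cxcl10 at 3815 CPM (3377 to 4295).

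Plp1 stood at 35593 CPM in the crushed and 44507 CPM in the chip cells of cluster 23, and Mag, a myelin adhesion protein, at 3908 and 3780 CPM. Genes taken before the data were examined as sources of free RNA (haemoglobin, S100a8, S100a9, Ngp and Camp among them) stood in LepR-like cells at 93.4 CPM (74.9 to 115) in crushed, 82.4 (58.0 to 114) in chips, 164 (119 to 219) in undigested and 221 (201 to 242) in digested flushed marrow. In Lin-CD45- marrow they stood at 7.55 CPM (0.191 to 42.0), with 1 UMI in 25 cells. There the smallest count of Hba-a1 above 0 was 36 UMIs. Lin-CD45-, crushed and chip libraries lacked low counts of some abundant genes, so their levels cannot be set against those of the flushed pair. Of all non-haematopoietic-like cells, LepR-like cells were 48.1% in crushed, 10.6% in chips, 82.2% in undigested and 54.0% in digested flushed marrow.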
